A study of Mus musculus with 12 samples.

How the data were processed

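Polyadenylated RNA from IL-2-expanded splenic natural killer (NK) cells of mice was sequenced in 12 libraries, with 3 biological replicates in each of 4 groups. The groups were wild-type and Mirc11-/- cells, each left unstimulated or stimulated through the activating receptor NKG2D for 6 h, and the strain label of every sample was C57BL/6. Per the submitters' processing notes, the authors used bcl2fastq, Trim Galore 0.4.1, Bowtie2 2.2.8 and RSEM 1.3.0 with the GRCm38 genome. The deposited table held RSEM expected counts for 50674 genes by Ensembl identifier and symbol, not scaled between libraries. Every value in it was a whole number, so the estimated counts had been rounded by the authors before deposit and no further rounding was needed. The annotation release and the strand setting were not given in the sources used here, so antisense or overlapping transcripts were not separable from the genes they overlap. Totals per library ranged from 15139281 to 25342991 counts, and floors given with the results cover counting error only.

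Gene coordinates, biotypes and 3' untranslated regions were taken from GENCODE vM21, which holds 55450 genes and matched 17401 of the 17457 genes tested; 90 symbols were shared by more than 1 identifier, and genes were therefore joined by identifier. Genes were filtered with filterByExpr by group, scaled with TMM factors, and fitted with the robust quasi-likelihood model of edgeR 4.0.16 under R 4.3.3, with 1 mean per group and a shared estimate of the spread over all 12 libraries. Contrasts tested were stimulation in wild-type cells, stimulation in Mirc11-/- cells, the difference between these responses (the interaction), and Mirc11-/- minus wild-type in unstimulated cells, in stimulated cells and averaged over both treatments. P values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05, and are two-sided. Levels are given as CPM (counts scaled by the TMM-adjusted library size), as mean ± SD of 3 libraries, and fold changes as log2 with the standard error (SE) of the fit.

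The filter, the model, the contrasts, 22 gene lists, the rule for named genes and the first set of alternative settings were all fixed before the data were examined. Named genes were a fixed set (Ifng, Csf2, Tnf, Ccl3, Ccl4, Ccl5, Xcl1, Prf1, Gzmb, Klrk1, Tnfaip3, Cblb, Itch, Traf6, Nfkb1, Fos, Jun and the microRNA genes of the cluster). To these were added, per contrast, the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between the libraries compared, a condition applied within each treatment for the averaged contrast and not applied to the interaction. Gene models without a name and near-identical multigene copies were left out of that ranking. Within each list, up to 4 members past the threshold with the smallest p, or where none passed up to 2 members, were also named. A gene was taken as near-identical to another when over 50% of its 31-mers occurred in transcripts of other genes, a limit set after the data were in hand; it excluded 25 candidates, while 50 of the 557 genes checked were over it. In the text the genes named by this rule were partly summarised by list, some are not reported here, and the few others named were chosen after their values were seen.

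Lists were tested with camera in limma 3.58.1 on edgeR z-scores with a preset inter-gene correlation of 0.01, and the p values were adjusted over all 126 list tests; an estimated correlation was used as an alternative. The erythroid and platelet list, with 2 measured members, was not tested. The lists covered NK cytokines and chemokines, cytolytic granule genes, NF-kB members and feedback genes, AP-1 and immediate-early genes, ubiquitin modifiers and the TRAF6 pathway, NKG2D proximal signalling, NK identity and receptors, activation and checkpoint genes, earlier-named targets of the deleted microRNAs, glycolysis and nutrient transport, cholesterol synthesis and uptake, interferon-stimulated genes, cell-cycle genes, the unfolded-protein and integrated stress response, and heat-shock and RNA-quality genes. Markers of T cells, B cells, macrophages and monocytes, dendritic cells, neutrophils and mast cells, and erythroid cells and platelets, and the genes beside the deleted locus, completed the set. For microRNA sites, 12794 genes with an annotated 3' untranslated region were searched for 7-mers matching the seed of miR-23a, miR-27a or miR-24. The difference in median log2 fold change between genes with and without a site was ranked, one-sided, among the 7-mers made by shuffling the site's letters (209, 449 and 119 shuffles). The ranking by excess over the shuffles' median and the adjustment over 9 tests were settled after the first values were seen.

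The alternative settings fixed at that time were DESeq2 size factors, no composition factor, no filter, a stricter filter, the DESeq2 1.42.0 Wald test, limma voom, a non-robust fit, a test against a 1.5-fold change, replicate number as a block across groups or within genotype, a fit of only the 2 groups compared, and leaving out each library in turn. A covariate for background reads (log2 CPM of 548 vomeronasal receptor genes, which NK cells are not known to express) and a restriction to genes with a mean log2 CPM of at least 2 were added after the data were seen. The procedure was tested on simulated counts with known changes. At a true 2-fold change it recovered 56.7% of changed genes for stimulation in wild-type cells, 56.2% in Mirc11-/- cells, 34.8% for the interaction, 59.4% between genotypes in unstimulated cells, 66.1% in stimulated cells and 78.1% for the average. At a true 1.5-fold change the interaction recovered 6.25% and at a 4-fold change 83.3%, and between 3 and 14 unchanged genes were called per contrast of about 16946 to 16999 genes. A list raised 1.5-fold was recovered with an adjusted p of 5.23e-27, with 1 other list past the threshold, and a simulated site effect of 0.1 log2 was recovered as 0.109 with a rank p of 0.00222. Simulated genes were drawn independently of one another, without background reads or an outlying library. The simulation therefore cannot show how list tests or false calls behave where genes are correlated or libraries differ in background. No library was left out.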

Results

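Gene expression was measured by RNA sequencing in NK cells expanded from mouse spleen with IL-2. NK cells are cytotoxic lymphocytes that secrete inflammatory cytokines, and NKG2D, encoded by Klrk1, is one of their activating receptors. Mirc11 is the microRNA cluster that encodes miR-23a, miR-27a and miR-24-2. Wild-type and Mirc11-/- cells were each sampled unstimulated and after 6 h of NKG2D stimulation, with 3 libraries per group. Totals averaged 22.6 ± 3.32 (SD) and 20.98 ± 1.08 megacounts in unstimulated and stimulated wild-type libraries, and 16.9 ± 1.70 and 17.3 ± 0.952 megacounts in unstimulated and stimulated Mirc11-/- libraries. Of the 50674 genes in the table, 42168 had a count in any library and 17457 passed the filter and were tested.

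The deleted cluster lies on chromosome 8 at 84208518 to 84208921 (GRCm38). Mir27a (ENSMUSG00000065444) had 2, 3 and 3 counts in unstimulated wild-type replicates 1 to 3, 1, 0 and 4 counts in the stimulated ones, and 0 counts in each of the 6 Mirc11-/- libraries. Mir24-2 had 1 count, in stimulated wild-type replicate 3, and Mir23a had 0 counts in all 12 libraries, so none of the microRNA genes was tested. Transcripts on both sides of the cluster differed between genotypes. Gm37352 (84200869 to 84203049), an unnamed transcript model upstream of the cluster, was higher in Mirc11-/- cells by 1.62 log2 ± 0.101 (SE; adjusted p = 6.31e-07, averaged over both treatments). Gm26532 (84208920 to 84209609), a long noncoding RNA model that borders Mir24-2, decreased by 1.67 log2 ± 0.185 (adjusted p = 0.000119). Zswim4, the next protein-coding gene (ENSMUSG00000035671, 84210678 to 84237055), decreased by 0.57 log2 ± 0.0621 (adjusted p = 0.000103). Gm37352 and Gm26532 were chosen after their values were seen. An overlapping transcript read from the edited locus would be counted with them, which was not tested.

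The response of wild-type cells to NKG2D stimulation included large rises of secreted mediators. Ccl1, a T-cell-attracting chemokine (ENSMUSG00000020702, chromosome 11, 82176657 to 82305690), rose from 2.79 ± 0.720 to 241 ± 46.3 CPM (SD, n = 3). Crtam, an adhesion receptor of activated cytotoxic lymphocytes, rose from 8.56 ± 1.93 to 196 ± 39.4 CPM. Ccl9, Xcl1, Csf2 (the cytokine GM-CSF) and Ccl3 rose by 4.45 ± 0.331, 3.94 ± 0.184, 3.67 ± 0.25 and 3.25 ± 0.225 log2 (SE; highest adjusted p 3.02e-06). Interferon gamma, Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), rose from 38.2 ± 2.39 to 180 ± 39.3 CPM, a 4.71-fold change (adjusted p = 1.35e-06). Tnf rose by 0.64 log2 (adjusted p = 0.00428). Of the 17 measured NK cytokines and chemokines, 15 rose and none fell, with the same counts adjusted over the list alone (list adjusted p = 8.26e-27, and adjusted p = 0.0316 with an estimated correlation).

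NF-kB members and feedback genes also rose in stimulated wild-type cells. Of 21 measured, 16 rose and 2 fell (18 and 2 adjusted over the list alone), among them Relb, Icam1, Nfkb2 and Traf1 with rises of 1.46, 1.39, 1.37 and 1.25 log2. The list's adjusted p was 3.65e-18, and the adjusted p = 0.155 with an estimated correlation. Tnfaip3, which encodes the deubiquitinase A20, rose by 1.19 log2 ± 0.107 (adjusted p = 3.19e-06), whereas Cblb, Itch and Traf6 had log2 changes of -0.05, -0.03 and -0.12 (adjusted p 0.739, 0.767 and 0.194). The 25 ubiquitin modifiers and TRAF6 pathway genes comprised 6 that rose (Tab1, Traf2 and Peli1 besides Tnfaip3 among them) and 2 that fell, also when adjusted over the list alone (list adjusted p = 0.125). AP-1 and immediate-early genes were mostly lower at 6 h, with 6 of 25 up and 13 down, also when adjusted over the list alone. Egr1 fell by 2.74 log2, Fosb by 2.39 and Fos by 2.11, while Egr2 and Nr4a1 rose by 2.59 and 2.02. That list's adjusted p was 0.007, with adjusted p = 0.505 with an estimated correlation, and without stimulated wild-type replicate 1 its adjusted p was 0.108. With the level of vomeronasal receptor reads, a measure of background described further on, as a covariate, its adjusted p was 0.935.

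Other large rises in wild-type cells were those of the transcriptional repressor Bcl6 (3.47 log2), the hexose transporter Slc2a6 (3.44), the Rab GTPase-activating protein Tbc1d4 (3.34) and the neuropeptide receptor Vipr2 (3.29). The largest falls were in Mycn (3.14 log2 lower), the prostaglandin receptor Ptger3 (3.04 lower) and Egr1, followed by Bcar3, Hbegf, Lrp8, Fosb, Etv5 and Osm (2.12 to 2.54 lower). All 20 cholesterol synthesis and uptake genes fell, also when adjusted over the list alone, including Acat2 by 2.01 log2 and Lss by 1.88 (list adjusted p = 4.05e-28, and adjusted p = 0.12 with an estimated correlation). Of 23 cell-cycle genes 10 fell (11 adjusted over the list alone), led by the replication licensing genes Mcm2 and Mcm3 with falls of 1.34 and 1.29 log2 (list adjusted p = 1.24e-08, and adjusted p = 0.372 with an estimated correlation). The unfolded-protein and integrated stress response list had 11 of 18 members down and 1 up (13 and 1 adjusted over the list alone; list adjusted p = 6.37e-05, and adjusted p = 0.468 with an estimated correlation). With the background covariate that list's adjusted p was 0.714.

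Cytolytic effectors did not move as a group in wild-type cells (5 of 20 up, 6 down; 6 and 6 adjusted over the list alone; list adjusted p = 0.762). Prf1 (perforin) fell by 0.62 log2 and Gzmb (granzyme B) by 0.52 log2, and Stx11 and Srgn rose by 0.81 and 0.70 log2. Leaving out single libraries ended the calls of Prf1 in 2 of 6 cases (adjusted p up to 0.0759, without stimulated wild-type replicate 1), of Gzmb in 5 of 6 (up to 0.153, without the same library) and of Klrk1, called 0.32 log2 higher, in 5 of 6 (up to 0.225, without unstimulated wild-type replicate 3). With the background covariate Prf1 and Gzmb changed by -0.02 and 0.03 log2 (adjusted p 0.925 and 0.927). In total 2814 genes rose and 2745 fell (edgeR), of which 1118 were called against a 1.5-fold change. Stimulated libraries of both genotypes carried more reads in genes not expected in NK cells. Vomeronasal receptor genes summed to 24.4 to 40.3 CPM in stimulated against 13.1 to 18.5 CPM in unstimulated wild-type libraries, so rises of low-expressed genes accompany a rise in background reads.

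In Mirc11-/- cells, stimulation raised Ccl1 from 3.19 ± 1.19 to 109 ± 11.4 CPM and Crtam from 9.37 ± 1.93 to 136 ± 19.8 CPM (SD, n = 3). Xcl1 and Csf2 rose by 2.54 ± 0.174 and 2.18 ± 0.258 log2 (SE; adjusted p 2.44e-07 and 3.67e-05). Ifng changed by 0.37 log2 ± 0.166 and Ccl4 by 0.51 ± 0.236 without passing the test (adjusted p 0.0887 and 0.102), Ccl3 rose by 0.57 ± 0.211 (adjusted p = 0.0439), and Tnf fell by 0.49 ± 0.15 (adjusted p = 0.0155). The values of Ifng, Ccl4, Ccl3 and Tnf changed with the background covariate and their calls with single libraries, while the fold of Csf2 stayed. The vomeronasal level did not overlap between unstimulated and stimulated Mirc11-/- libraries (14.3 to 17.8 against 48.6 to 90.6 CPM). The covariate therefore cannot fully separate background from stimulation. With the vomeronasal level as a covariate Ifng, Ccl4 and Ccl3 changed by 1.54, 1.87 and 1.65 log2 (adjusted p 0.00345, 0.0416 and 0.064), Csf2 by 2.19 (0.0949) and Tnf by -0.14 (0.863). Without stimulated Mirc11-/- replicate 1, Ifng and Ccl4 were called higher (adjusted p 0.0119 and 0.0209), whereas the call of Ccl3 ended in 5 of 6 leave-outs (up to 0.205) and that of Tnf in 1 (0.0514), both without stimulated Mirc11-/- replicate 2. Of 17 cytokines and chemokines 9 rose and 3 fell (Tnf, Lta and Tnfsf10), or 10 and 3 adjusted over the list alone, with a list adjusted p of 2.53e-05 and adjusted p = 0.332 with an estimated correlation.

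The largest other rises in Mirc11-/- cells were in the inhibitory Fc receptor gene Fcgr2b (0.0965 to 2.26 CPM), the transcription factor gene Tcf7 (3.76 log2), Slc2a6 (3.72), Bend4 (3.70), Tbc1d4 (3.38), Gadd45b (3.29), Bcl6 (3.23) and Fstl1 (2.90). Mycn, Hbegf, Ptger3, Tnfrsf11b and Egr1 fell by 3.54, 3.38, 3.31, 3.28 and 3.12 log2, and Osm, Cth, Tmem119, Fosb and Adora2b by 2.64 to 2.78. NF-kB members and feedback genes had 15 of 21 up and 3 down, also when adjusted over the list alone (list adjusted p = 4.48e-07, and adjusted p = 0.347 with an estimated correlation). AP-1 and immediate-early genes had 5 of 25 up and 15 down, also when adjusted over the list alone (6.22e-07, and adjusted p = 0.352 with an estimated correlation). Tnfaip3 rose by 1.32 log2. In its list 6 of 25 ubiquitin modifiers and TRAF6 pathway genes rose and 4 fell, also when adjusted over the list alone (list adjusted p = 0.464). All 20 cholesterol genes fell, also when adjusted over the list alone, with Acat2 2.48 and Lss 2.28 log2 lower (3.95e-34, and adjusted p = 0.0936 with an estimated correlation). The unfolded-protein and integrated stress response list had 16 of 18 members down, also when adjusted over the list alone (3.41e-10, and adjusted p = 0.347 with an estimated correlation). The cell-cycle list had 13 of 23 down (14 adjusted over the list alone; 8.63e-08, and adjusted p = 0.391 with an estimated correlation). Prf1 and Gzmb fell by 1.23 and 1.24 log2, and the cytolytic list had 4 of 20 up and 7 down (5 and 7 adjusted over the list alone; list adjusted p = 0.0993; 0.0205 without stimulated replicate 3, and 0.00272 in the opposite direction with the background covariate).

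Stimulation changed 7958 genes in Mirc11-/- cells, 4106 up and 3852 down. Of the genes that rose in wild-type cells, 2214 also rose in Mirc11-/- cells, and 2248 genes fell in both, against 662 and 606 if the calls were independent, although genes are not independent of one another. Vomeronasal receptor reads rose here too, from 14.3 to 17.8 CPM in unstimulated to 48.6 to 90.6 CPM in stimulated libraries, and 2026 of the 4106 rises lay below a mean log2 CPM of 2. Markers of other cell types rose as well. All 6 measured B-cell markers were called higher, also when adjusted over the list alone, mostly at very low levels (Pax5 from 0.0184 to 1 CPM) but with Ighm rising from 65.4 to 103 CPM. The list's adjusted p was 0.0183, with adjusted p = 0.31 with an estimated correlation and 0.0634 without unstimulated Mirc11-/- replicate 1. Of 7 dendritic-cell markers 6 rose (7 adjusted over the list alone), with a list adjusted p of 0.0239, adjusted p = 0.352 with an estimated correlation and 0.0556 without stimulated Mirc11-/- replicate 1. With the vomeronasal level as a covariate, an alternative added after the data were seen, 1244 genes were called. The calls of Prf1 (-0.01 log2, adjusted p = 0.992), Gzmb (-0.11, 0.837), Fos, Jun, Fcgr2b, Fstl1, Hbegf, Osm, Cth, Tmem119 and Tnfrsf11b ended under it, as did those of the AP-1 (0.792), stress response (0.95), B-cell (0.38) and dendritic-cell lists (0.51). Fcgr2b, Tnfrsf11b, Hbegf, Fos, Osm, Fstl1, Tmem119, Jun and Cth were then at 3.22, -2.95, -2.39, -1.39, -1.36, 0.97, -0.79, -0.71 and -0.36 log2.

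Whether the loss of Mirc11 altered the response to NKG2D itself was tested as the interaction. Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355), a chemokine that NK cells release on activation, rose from 35.2 ± 5.18 to 335 ± 61.5 CPM in wild-type cells and from 42.8 ± 5.27 to 63.6 ± 20 CPM in Mirc11-/- cells (SD, n = 3). Its response was smaller in Mirc11-/- cells by 6.39-fold (-2.68 log2 ± 0.301 SE, adjusted p = 0.0223). The response of Ifng was smaller by 3.66-fold (-1.87 log2 ± 0.235, adjusted p = 0.0223), with 46.0 ± 1.54 CPM in unstimulated and 59.3 ± 13.5 CPM in stimulated Mirc11-/- cells. As a group, the 17 cytokines and chemokines had a median interaction of -1.13 log2, and 11 were lower and 1 higher adjusted over the list alone (list adjusted p = 3.78e-24, and adjusted p = 0.0316 with an estimated correlation). The cytokine lists of wild-type stimulation and of the interaction were the 2 of 56 list calls, among all 126 tests, that held with an estimated correlation.

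**Figure D1:**
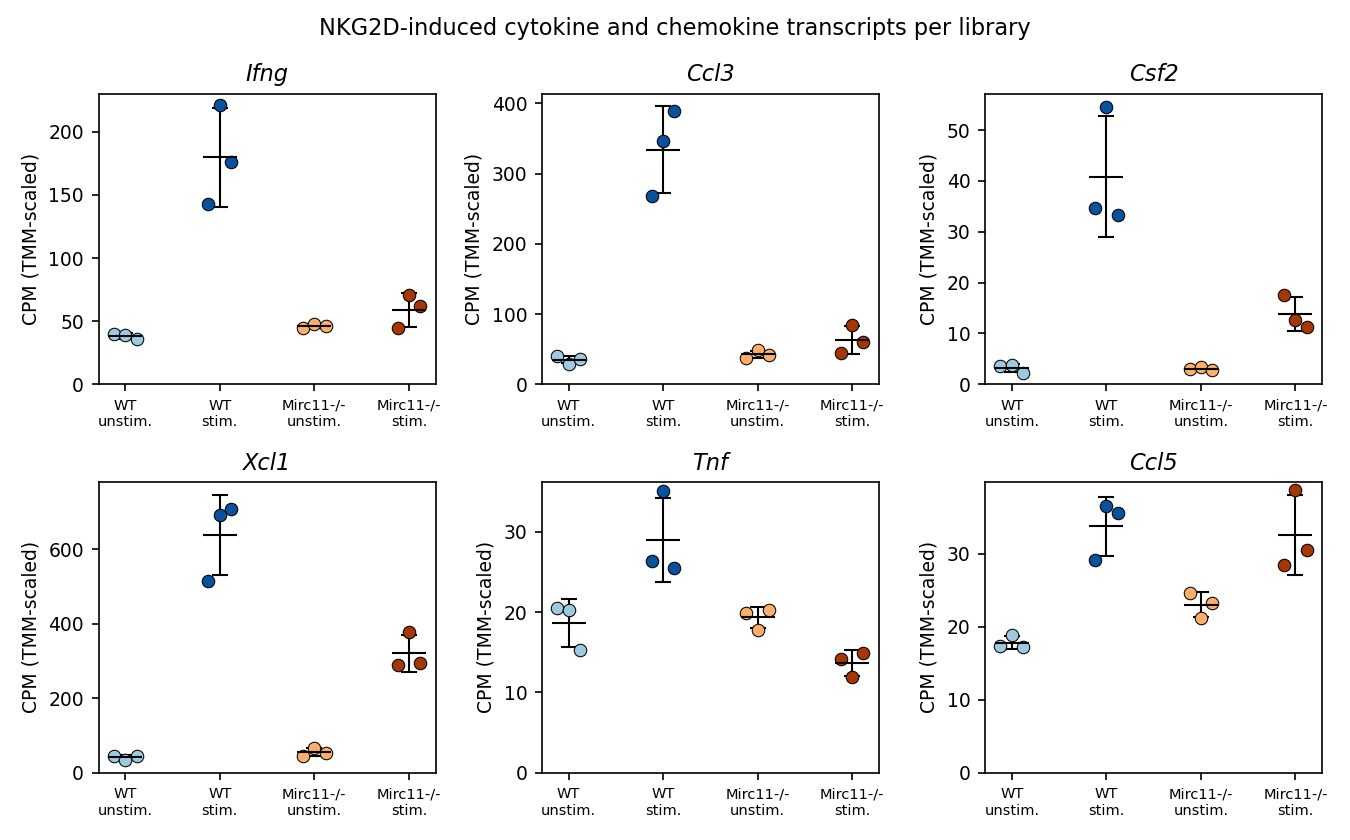
Levels of Ifng, Ccl3, Csf2, Xcl1, Tnf and Ccl5 in CPM on linear axes, with points for the 12 libraries and bars for the mean and SD of 3 in each of the 4 groups. Ccl3 averaged 335 CPM in stimulated wild-type and 63.6 CPM in stimulated Mirc11-/- cells, and Ifng 180 and 59.3 CPM.

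Other cytokines had negative estimates that did not pass the test over all genes, and passed under some settings. Ccl4, Csf2, Xcl1 and Tnf had interactions of -1.85, -1.49, -1.40 and -1.13 log2 (adjusted p 0.174, 0.32, 0.13 and 0.167). Egr2 and Irf4, transcription factors induced by antigen receptors, had -1.13 and -1.14 log2 (0.174 and 0.13). All 6 passed in DESeq2 (highest adjusted p 0.00894), and Ccl4, Xcl1 and Tnf with replicate number as a block within genotype (each 0.0224). Calls also appeared without stimulated wild-type replicate 1 (Egr2 0.0125, Xcl1 0.0198, Irf4 0.0405 and Ccl4 0.041) and without stimulated Mirc11-/- replicate 2 (Ccl4 0.0212). In the main edgeR fit no gene of the NF-kB list passed (0 lower over all genes, 4 lower adjusted over the list alone; list adjusted p = 0.000257, and adjusted p = 0.397 with an estimated correlation). The same was true, in that fit, of the AP-1 list (10 lower adjusted over the list alone; 9.91e-09, and adjusted p = 0.332 with an estimated correlation) and of the cholesterol list (11 lower adjusted over the list alone; 1.71e-10, and adjusted p = 0.332 with an estimated correlation). Of the named members of these lists, Egr2, Nfkbia, Nfkbiz and Dusp6 passed in 3, 2, 1 and 1 of 23 alternative settings (lowest adjusted p 0.000249, 0.0112, 0.047 and 0.0064). With the background covariate the adjusted p of these lists were 0.944, 0.31 and 0.199. The response of Tnfaip3 differed by 0.13 log2, of Cblb by 0.22, of Itch by -0.10 and of Traf6 by 0.01 (adjusted p 0.71, 0.508, 0.677 and 0.985), and the ubiquitin and TRAF6 list by a median of -0.10 log2 (adjusted p = 0.323; 0 members adjusted over the list alone).

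For the interaction, edgeR called 0 genes with a larger and 2 with a smaller response in Mirc11-/- cells, with 1858 genes at an unadjusted p under 0.05 against 873 expected by chance; limma voom called 2 and DESeq2 68. Both calls ended in 8 of 12 leave-outs, with adjusted p up to 0.147 (without unstimulated wild-type replicate 3), and held without unstimulated Mirc11-/- replicate 1, stimulated Mirc11-/- replicates 1 and 2 and stimulated wild-type replicate 1. The 8 were unstimulated Mirc11-/- replicates 2 and 3, stimulated Mirc11-/- replicate 3, unstimulated wild-type replicates 1, 2 and 3, and stimulated wild-type replicates 2 and 3. With the vomeronasal level as a covariate the interactions were -2.10 log2 ± 0.339 for Ccl3 and -1.25 ± 0.184 for Ifng (adjusted p 0.456 and 0.12), and the cytokine list had an adjusted p of 1.08e-17.

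Between unstimulated genotypes, Itln1 and Fcgr2b differed most in fold. Itln1, a secreted lectin (ENSMUSG00000038209, chromosome 1, 171518122 to 171535294), had 11.9 ± 1.13 CPM in wild-type cells (SD, n = 3) and 0 counts in the 3 Mirc11-/- libraries, at least 202-fold lower against a floor of 3 counts over the group (0.0587 CPM). Fcgr2b (ENSMUSG00000026656, chromosome 1, 170958617 to 170976547) had 11.3 ± 1.12 against 0.0965 ± 0.122 CPM (adjusted p = 2.14e-05). The Fc-receptor-like gene Fcrl6 fell by 1.71 log2 ± 0.141 (SE; adjusted p = 3.28e-05), Notch3 by 2.36 ± 0.249, Tdrd9 by 1.82 ± 0.205 and the growth factor gene Pdgfb by 1.71 ± 0.18. Gja1, which encodes the gap-junction protein connexin 43, rose by 1.61 log2 ± 0.239, Sidt1 by 1.46 ± 0.127, the receptor gene Acvrl1 by 1.28 ± 0.176, and Adgre5 (CD97), which lies within 20 Mb of the deleted locus, by 1.19 ± 0.163. These 10 calls held in every leave-out.

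Of the remaining genes with the largest differences, Ifi206, Podnl1, Olfr1388, Zbtb18, Kcna3 and Hmgn1 were higher in unstimulated Mirc11-/- cells (0.78 to 1.31 log2), and Csf2rb, Ctsg, Clic5 and Gzmf were lower (by 1.67 to 1.90 log2). Podnl1 is a neighbour of the deleted locus. Each of these calls ended in 2 to 6 of the 6 leave-outs, with adjusted p from 0.0758 for Ifi206 to 0.268 for Zbtb18, the latter without unstimulated Mirc11-/- replicate 2. No cytokine gene fixed in advance was called before stimulation, with 0.27 log2 for Ifng, 0.28 for Ccl3, 0.41 for Xcl1, 0.37 for Ccl5 and 0.36 for Ccl4 (adjusted p 0.746, 0.82, 0.442, 0.258 and 0.768). Ccl5 was called with the background covariate (0.40 log2, 0.0212). Within the cytokine list Tnfsf10 (TRAIL) alone was called, 0.54 log2 higher, also when adjusted over the list alone (list adjusted p = 0.00109, and adjusted p = 0.352 with an estimated correlation), and its call ended in 5 of 6 leave-outs (up to 0.134). Itgam and Itga2 were 0.71 and 0.66 log2 higher and the Fc receptor gene Fcgr3 0.79 log2 lower within the NK identity list (2 up and 1 down of 25, 3 and 2 adjusted over the list alone; list adjusted p = 0.0421, and adjusted p = 0.601 with an estimated correlation; up to 0.527 without unstimulated wild-type replicate 3), each losing its call in at least 5 of 6 leave-outs (adjusted p up to 0.246).

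No ubiquitin modifier or TRAF6 pathway gene was called between unstimulated genotypes by edgeR (0 of 25, 0 adjusted over the list alone; list adjusted p = 0.668); Tnfaip3, Cblb, Itch and Traf6 had differences of 0.04, -0.25, 0.08 and -0.02 log2 (adjusted p 0.988, 0.322, 0.856 and 0.992). Over all genes 54 were higher and 139 lower in Mirc11-/- cells. DESeq2 called 382 and limma voom 178, and single leave-outs gave as few as 72 genes without unstimulated Mirc11-/- replicate 2, 75 without replicate 3 of that group, 75 without unstimulated wild-type replicate 1 and 113 without replicate 2. A fit of the 6 unstimulated libraries alone called 328 and ended the calls of Ctsg (0.0537), Clic5 (0.0928) and Itgam (0.114).

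After stimulation, Mirc11-/- cells had lower levels of inflammatory mediators than wild-type cells. Ccl3 fell by 2.40 log2 ± 0.217 (SE; adjusted p = 0.000109), Ccl9 by 1.88 ± 0.281, Ifng by 1.60 ± 0.167 (adjusted p = 0.000214), Csf2 by 1.56 ± 0.221, Ccl4 by 1.48 ± 0.238, Tnf by 1.08 ± 0.148 and Xcl1 by 0.99 ± 0.164, where Xcl1 averaged 322 ± 49.1 CPM against 640 ± 107 CPM (SD, n = 3). Ccl1 and Tnfsf14 were also lower. In total 9 of 17 cytokines and chemokines fell and 0 rose, also when adjusted over the list alone (list adjusted p = 3.47e-12, and adjusted p = 0.12 with an estimated correlation). Ccl5 did not pass, at -0.05 log2 (adjusted p = 0.8). With the vomeronasal level as a covariate the list's adjusted p was 2.3e-06, and of the 7 genes given here with values Ifng alone passed (-0.93 log2, 0.0269). Ccl3 was at -1.78 (0.0696), Csf2 at -1.55 (0.469), Ccl9 at -0.89 (0.68), Tnf at -0.87 (0.39), Xcl1 at -0.73 (0.74) and Ccl4 at -0.70 (0.786).

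Some effector and signalling genes were also lower in stimulated Mirc11-/- cells, and their calls ended with the background covariate. Of 20 cytolytic granule genes 8 fell (12 adjusted over the list alone), with Gzmf 2.04, Gzmg 1.79, Prf1 1.11, Stx11 0.67 and Rab27a, which docks lytic granules, 0.61 log2 lower (list adjusted p = 1.73e-09, and adjusted p = 0.352 with an estimated correlation). Gzmb at -0.50 log2 did not pass (adjusted p = 0.085) and was called without stimulated Mirc11-/- replicate 2 (0.04). The granzyme genes Gzmd to Gzmg are related copies and share part of their sequence. Of 25 AP-1 and immediate-early genes 11 fell, among them Atf3, Egr2, Jun and Dusp6 by 1.20, 0.86, 0.68 and 0.53 log2 (14 lower and 1 higher adjusted over the list alone; 2.46e-08, and adjusted p = 0.332 with an estimated correlation). Among 21 NF-kB members and feedback genes 5 fell, including Nfkbia by 0.55, Cflar by 0.36 and Birc3 by 0.33 log2 (13 adjusted over the list alone; 7.19e-06, and adjusted p = 0.352 with an estimated correlation). Leaving out single libraries ended these calls of Nfkbia (0.0686, without stimulated wild-type replicate 2), Cflar (0.0573, without the same library), Birc3 (0.0681, without stimulated wild-type replicate 3) and Gzmg (0.0563, without stimulated wild-type replicate 2). The activation markers Havcr2, Irf4 and Cd69 were 1.04, 0.93 and 0.84 log2 lower (5 of 20 activation and checkpoint genes fell, 7 lower and 1 higher adjusted over the list alone; 0.00113, and adjusted p = 0.318 with an estimated correlation). With the covariate Prf1, Atf3, Egr2, Dusp6, Nfkbia and Irf4 were at -0.42, -0.52, -0.26, -0.19, -0.17 and -0.48 log2, and Gzmf, Gzmg, Stx11, Rab27a, Jun, Cflar, Birc3, Havcr2 and Cd69 did not pass either (adjusted p 0.469 to 0.875). Of these, Birc3, Cflar and Cd69 kept most of their fold (-0.31, -0.31 and -0.62 log2), Havcr2, Jun, Gzmf and Gzmg were at -0.48, -0.45, -1.23 and -0.82, and Stx11 and Rab27a at -0.26 and -0.19. The cytolytic, AP-1, NF-kB and activation lists then had adjusted p of 0.56, 0.332, 0.419 and 0.437. In a fit of the 6 stimulated libraries alone of the 84 genes followed for this contrast 37 lost their calls, among them Rab27a, Egr2, Dusp6, Nfkbia, Cflar and Birc3. The 84 include genes not called in the main fit, such as Ccl5, Gzmb and Tnfaip3, which had no call to lose.

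Genes of metabolic and stress lists were lower as well, most of them in cholesterol synthesis. Of 20 cholesterol genes 17 were lower (19 adjusted over the list alone), including Hmgcs1 by 1.06 and Sqle by 0.60 log2 (1.2e-17, and adjusted p = 0.204 with an estimated correlation). Of the stress genes, 8 of 18 unfolded-protein and integrated stress response genes were lower (15 adjusted over the list alone; 2.02e-09, and adjusted p = 0.352 with an estimated correlation), with Chac1 1.15 and Herpud1 0.98 log2 lower. Herpud1 lies within 20 Mb of the deleted locus on chromosome 8. The call of Chac1 ended in 3 of 6 leave-outs (up to 0.0938, without stimulated Mirc11-/- replicate 1). In glycolysis and nutrient transport, Slc7a5 and Slc2a3 fell by 0.96 and 0.64 log2 (2 of 20, 13 adjusted over the list alone; 3.07e-08, and adjusted p = 0.381 with an estimated correlation), the latter call ending without stimulated wild-type replicate 3 (0.0968). With the background covariate the glycolysis and stress response list tests changed direction (adjusted p 0.533 and 0.714), the cholesterol list had 3.46e-05, and Hmgcs1, Sqle, Chac1, Herpud1, Slc7a5 and Slc2a3 did not pass (-0.59, -0.46, -0.22, -0.34, -0.45 and -0.11 log2). In the ubiquitin and TRAF6 list, Tax1bp1, an adaptor of A20, was the 1 of 25 members called, 0.44 log2 lower (adjusted p = 0.0153; 0.075 without stimulated wild-type replicate 2, 0.833 with the covariate), also when adjusted over the list alone (list adjusted p = 0.202). The fit of stimulated libraries alone ended the calls of Chac1, Slc2a3 and Tax1bp1 (0.0549, 0.107 and 0.107). Tnfaip3, Cblb, Itch and Traf6 differed by 0.17, -0.04, -0.02 and -0.01 log2 (adjusted p 0.287, 0.816, 0.891 and 0.921).

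The largest falls after stimulation were those of Itln1 (9.98 ± 0.218 CPM against 3 counts in stimulated Mirc11-/- replicate 3 and 0 in the others), Fcgr2b (2.75 log2), Tmem119 (2.75), the serine protease gene Ctsg (2.53), Ccl3, Clic5 (2.11) and Tdrd9 (2.08). Tmem119 and Clic5 lost their calls without stimulated wild-type replicate 3 (0.0513) and stimulated Mirc11-/- replicate 1 (0.0859). Mid1, Gja1 and Fstl1 rose by 1.63, 1.47 and 1.37 log2 and kept their calls in every leave-out, but not with the background covariate (0.77, 1.17 and 0.30 log2, adjusted p 0.837, 0.421 and 0.893). Me3, Cdk15, Ifi206, Olfr975, Ifi213, RP24-340L11.5 and Lmtk3 were also called higher and lost their calls in 1 to 4 of 6, at most at 0.147 (RP24-340L11.5, without stimulated wild-type replicate 2). With the covariate none of these 7 passed, and Me3, Cdk15, Olfr975 and RP24-340L11.5 were at 0.33, -0.03, 0.05 and 0.01 log2, while Ifi206 and Lmtk3 stayed at 1.35 and 1.01 and Ifi213 rose in fold. Itln1 and Fcgr2b kept their calls (9.77e-05 and 0.00503), and Tmem119, Ctsg, Clic5 and Tdrd9 did not (0.712, 0.45, 0.859 and 0.0532), at -1.79, -1.83, -1.11 and -1.60 log2. In the fit of stimulated libraries alone Tmem119, Fstl1, Me3, Cdk15, Olfr975, RP24-340L11.5 and Lmtk3 did not pass either (0.0531 to 0.101).

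In all, 679 genes were higher and 896 lower in stimulated Mirc11-/- cells; 28 of the 54 and 107 of the 139 called in unstimulated cells were called in the same direction, and 0 in the opposite one, against 2.1 and 7.13 under independence. Of the 679, 263 had a mean log2 CPM below 2, and the stimulated Mirc11-/- libraries carried more vomeronasal receptor reads (48.6 to 90.6 CPM) than the stimulated wild-type ones (24.4 to 40.3 CPM). Stimulated Mirc11-/- replicate 1 stood apart on the second principal component, at 52.1. The count was 714 without stimulated Mirc11-/- replicate 1, 2397 without its replicate 2, 337 without stimulated wild-type replicate 2, 449 without its replicate 3, 215 in a fit of the 6 stimulated libraries alone, and 34 with the vomeronasal level as a covariate.

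Averaged over both treatments, 6 Mirc11-/- libraries were compared with 6 wild-type libraries. Gja1, Ifi206, Podnl1, Ifi213, Sidt1, the integrin gene Itgax, Adgre5, Olfr1388, Ifi209 and Hsh2d had the largest rises (1.54 to 0.85 log2). Fcgr2b fell by 4.75 log2 ± 0.287 (SE), the peptide transporter gene Slc15a2 by 3.45 ± 0.783, Tmem119 by 2.09 ± 0.33, Tdrd9 by 1.95 ± 0.148, and Clic5, Notch3, Gzmf and Csf2rb by 1.81 to 1.91, with Ctsg between Slc15a2 and Tmem119. Slc15a2 lost its call in 9 of 12 leave-outs (up to 0.087, without stimulated wild-type replicate 3) and Ifi209 in 5 (up to 0.0745, without stimulated Mirc11-/- replicate 1). Tax1bp1 and Ube2v1, the latter a partner of the ubiquitin-conjugating enzyme used by TRAF6, were 0.37 and 0.28 log2 lower (adjusted p 0.00433 and 0.0284). They were 2 of 25 members of the ubiquitin list, also when adjusted over the list alone (list adjusted p = 0.302), and the call of Ube2v1 ended in 8 of 12 leave-outs (up to 0.0794, without stimulated wild-type replicate 2). Bcl2l11, the proapoptotic gene Bim and an earlier-named target, was 0.39 log2 higher (adjusted p = 0.00162) and Prdm1 0.60 log2 lower, the latter call ending in 9 of 12 leave-outs (up to 0.105, without unstimulated Mirc11-/- replicate 2). The target list as a whole had 1 up and 1 down of 19 (3 and 1 adjusted over the list alone; list adjusted p = 0.274). With the background covariate the calls of Tax1bp1 (0.146), Ube2v1 (0.568), Bcl2l11 (0.0757), Prdm1 (0.641), Podnl1 (0.0983), Ifi213 (0.0686), Olfr1388 (0.141), Ifi209 (0.292), Slc15a2 (0.294), Tmem119 (0.142), Clic5 (0.148) and Csf2rb (0.059) ended. The fold of Ifi213 rose, while those of Podnl1, Ifi209, Slc15a2, Csf2rb, Tmem119 and Clic5 were then 1.04, 1.03, -3.05, -1.69, -1.57 and -1.37 log2, and those of Olfr1388, Tax1bp1, Bcl2l11, Prdm1 and Ube2v1 0.57, -0.27, 0.31, -0.30 and -0.14.

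In total 428 genes were higher and 857 lower in the averaged contrast. Counts fell to 680 without unstimulated wild-type replicate 1, 692 and 796 without unstimulated Mirc11-/- replicates 2 and 3, 750 and 780 without stimulated wild-type replicates 3 and 2, 808 without unstimulated wild-type replicate 2, and 228 with the vomeronasal covariate. Called genes were more frequent near the deleted locus. Within 20 Mb of it, 81 of 363 tested genes were called, 27 higher and 54 lower, or 22.3% against 7.05% of 17038 genes elsewhere. Podnl1, Adgre5, Hsh2d, Zswim4, Il27ra, Dcaf15, Herpud1 and the interferon-induced gene Bst2 (1.19 log2 lower) lie in this interval. A stretch of chromosome 1 from 170958617 to 173647928 holds Fcgr2b, Itln1, Fcrl6, Ifi206, Ifi213 and Ifi209; 13 of its 65 tested genes were called (20% against 7.31% elsewhere), a stretch chosen after its genes were seen.

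**Figure D2:**
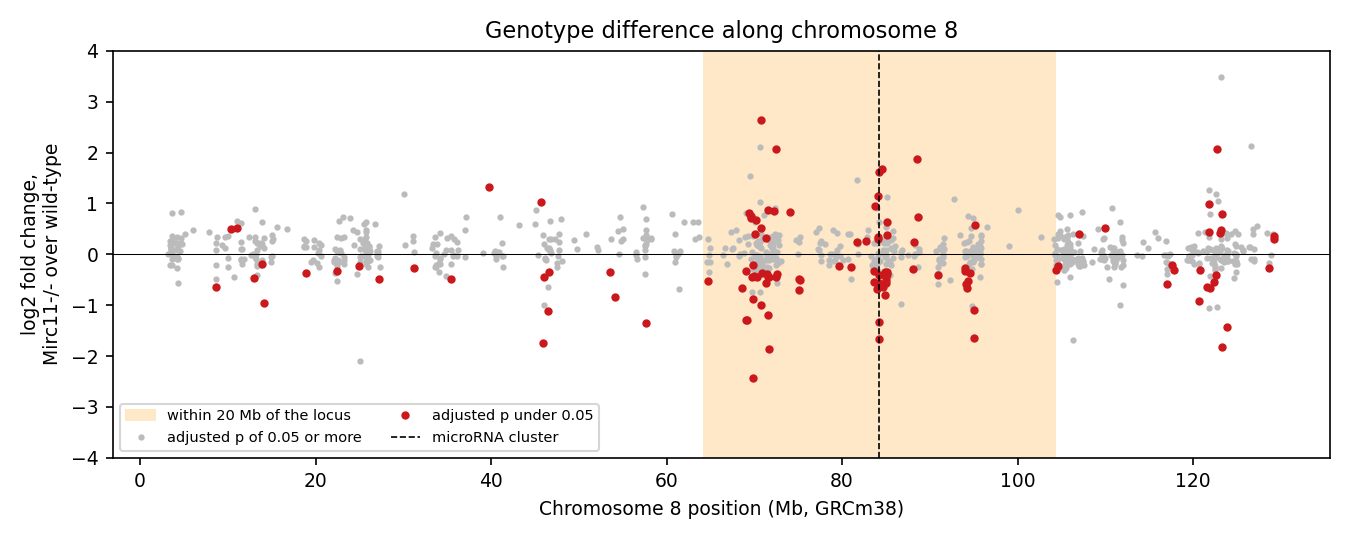
Log2 fold change of Mirc11-/- over wild-type cells, averaged over both treatments, against position on chromosome 8 in Mb for 953 tested genes, with called genes marked and the deleted locus and the 20 Mb on each side of it drawn. In this interval 22.3% of genes were called, against 7.05% elsewhere in the genome.

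Loss of the cluster would be predicted to raise transcripts with sites for its microRNAs, which was tested over 12794 genes. In the averaged contrast, genes with a miR-23a site had a median log2 fold change 0.0482 higher than genes without one, against a median of 0.03 for shuffled sites (one-sided rank permutation p = 0.0238, adjusted 0.08). For miR-27a the difference was 0.0457 against 0.0238 (0.0267, adjusted 0.08) and for miR-24 0.0254 against 0.0131 (0.075, adjusted 0.0938). None of the 9 tests over the averaged, unstimulated and stimulated contrasts passed after adjustment (lowest 0.08, highest 0.167). No leave-out brought any of them past the threshold (lowest 0.0571, without unstimulated Mirc11-/- replicate 2).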

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

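The tests of NK cell share, of linked DNA and of a single library, the shuffled-site control for low-expressed genes and the background covariate were chosen after the result was seen. Among the comparisons, a difference between the stimulation responses of the 2 genotypes, by the interaction test, was found for Ccl3 (-2.68 log2), Ifng (-1.87 log2) and the cytokine and chemokine list (median -1.13 log2). The stimulated level of Ccl3 was lower in all 3 Mirc11-/- libraries, the highest of which had 84.7 CPM against 268 CPM in the lowest stimulated wild-type library. For Ifng these values were 71.1 and 142.8 CPM. They are levels after stimulation, since unpaired libraries have no induction of their own.

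For the smaller induction of Ccl3 and Ifng, background reads that differ between libraries could be a cause, and with the vomeronasal covariate the interaction of Ifng went from -1.87 ± 0.235 to -1.25 log2 ± 0.184, the lower share kept at 66.7%, and that of Ccl3 from -2.68 ± 0.301 to -2.10 log2 ± 0.339 (78.5%). Both calls ended, with smaller estimates and unadjusted p of 6.9e-06 and 0.00012 (adjusted 0.12 and 0.456, against ranges of 2.28e-10 to 0.156 and 4.8e-16 to 0.456 over all settings). The vomeronasal level did not overlap between the stimulated genotypes, so the covariate cannot tell how much of the difference background made. Background thus stays open as a cause. Fewer NK cells in the Mirc11-/- cultures would lower NK transcripts alike by about the change to be explained, but the NK identity list had a median of -0.137 log2 (SD 0.384) in stimulated cells. A weaker stimulation as a whole would shrink the response of all genes, but the median ratio of responses in 785 genes was 1.2 (95% bootstrap interval 1.18 to 1.23), against 0.594 for the cytokine list. The interval resampled genes as if they were independent and does not cover the variation between libraries. The 785 genes were chosen for a large average response and a mean log2 CPM of at least 2, limits not applied to the cytokine list. The ratio was taken without the background covariate, and background was highest in stimulated Mirc11-/- libraries. Outside the cytokine list, Egr2 and Irf4 had interactions of -1.13 and -1.14 log2 and Tnfaip3 of 0.13, none called in the main fit. The ratio thus speaks only against a weakening uniform over genes, and a weaker stimulation of part of the response stays open. Loss of the cluster stays among the open explanations, as untested, beside background, handling and RNA quality.

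Other splits of the 12 libraries were tested for the interaction. Of 100 drawn splits, 4 called at least 2 genes, the real one with 2 included, and 1 of the others called 183. That split kept the stimulated genotypes apart and placed unstimulated Mirc11-/- replicate 3 with unstimulated wild-type replicates 1 and 2. With most unstimulated labels exchanged, its interaction adds up the genotype differences of both treatments. It is the same test as the averaged genotype contrast of the split with those unstimulated labels swapped, which also called 183. The 183 thus reflect a genotype difference and not a different response. For the cytokine list 1 of 100, the real one, had as small a camera p (1.2e-25, with 6.92e-22 in the nearest other). A random assignment of genotype labels can thus be excluded at that number of splits for the list. Other drawn splits that kept the stimulated genotypes apart had list p of 6.92e-22 to 8.23e-09, and splits that mixed them as low as 8.93e-07. The exchange therefore tests any genotype difference, not the interaction alone. For the count the share of 4 in 100 is under 0.05. Since such splits carry the genotype difference into the interaction, that share lends little weight to a count of 2.

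For the crowding of called genes around the deleted locus on chromosome 8, DNA of another strain carried along with the edited locus may be a cause. The odds of being called within 20 Mb were 3.79 times those elsewhere (95% interval 2.9 to 4.9, Fisher p = 7.18e-20), 0 of 68 other windows of the genome reached 22.3% (highest 15.2%), and for stimulation in wild-type cells the interval held 28.7% called genes against 31.9% elsewhere. The window with 15.2% lies on chromosome 8 beyond the interval, and the highest on any other chromosome was 11.4%, on chromosome 1. The first window of chromosome 8 had 5.86%. Expression level is argued against, since 0 of 10000 expression-matched gene sets had as many called genes (median 25, highest 46, against 81; permutation p = 1e-04, the smallest they can give). Direct targeting cannot be told apart as a source of the higher genes, since 37.5% of only 24 such genes had a site against 37.6% of 234 others (95% interval of the odds ratio 0.368 to 2.55; one-sided Fisher p = 0.586). An effect of the deletion on nearby chromatin was not tested, so differences of Podnl1, Adgre5, Hsh2d, Bst2, Il27ra, Dcaf15 and Herpud1 may stem from linked DNA, from loss of the microRNAs or from both.

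The 263 low-expressed genes higher in stimulated Mirc11-/- than in stimulated wild-type libraries may follow background reads, for instance from traces of genomic DNA or precursor RNA. Within groups, 91.9% of them correlated positively with the vomeronasal level against 80.4% of 6205 other low-expressed genes. With that level as a covariate 3 were called, but the covariate ended most calls of this contrast at any expression level, so that loss is not particular to these genes. A single library, stimulated Mirc11-/- replicate 1, cannot be told apart as the source, since the genes were chosen with it included. Without it 17.1% were called, few enough for such a source by the limit first set, but leaving out stimulated wild-type replicate 2 or 3 left 8.75% or 10.3%. The median of these genes without that Mirc11-/- library was 1.11 log2, against 1.34 with all libraries, a value that the choice of genes largely fixes. Release from the deleted microRNAs cannot be told apart, since 51.1% had a site against 40.1% of others (one-sided Fisher p = 0.00657), but shuffled sites gave a median excess of 9.97 percentage points against 11 (rank p = 0.391) with longer untranslated regions in these genes (median 2086 against 1151 bases).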

How the results depend on the processing

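The background covariate and the restriction to higher-expressed genes were chosen after the data were seen, and the cause was not tested for the changes below unless stated. A test against a 1.5-fold change, stricter by construction, called 1118 and 2528 genes for stimulation in wild-type and Mirc11-/- cells, 0 for the interaction, and 39, 54 and 81 between genotypes in unstimulated cells, in stimulated cells and on average. DESeq2 called 68 for the interaction and 382 and 2366 between unstimulated and stimulated genotypes, a fit without filter called 47 for the interaction, and a fit of only the 2 groups compared called 328 and 215 and ended the calls of 37 of the 84 genes followed between stimulated genotypes. Some of these 84 genes had no call to lose. With replicate number as a block within genotype the interaction had 13 genes. With replicate number as a block across groups the counts were 5696, 8070, 3, 176, 2142 and 1452 in the order above. The numbers were not treated as pairs, since residuals of the 18 same-number pairs correlated at -0.18 to 0.23 (median 0.049, against -0.041 for other pairs), although 8 of 12 libraries best matched one with their own number and wild-type pairs correlated at 0.0935 to 0.226, so shared handling by number stays open. An estimated correlation left 2 list calls. Without a composition factor 41.9% of called genes in stimulated wild-type cells were higher, against 50.6%. Stimulation in wild-type cells kept its count within 1.5 times under every setting but the 1.5-fold test.

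With the background covariate 1244 genes were called for stimulation in Mirc11-/- cells, 0 for the interaction (DESeq2, without the covariate, 68; 1858 at an unadjusted p under 0.05 without it), 317, 34 and 228 between genotypes in unstimulated cells, in stimulated cells and on average, and 32 lists. Under it some list tests changed direction, with adjusted p of 0.935 (AP-1) and 0.0348 (glycolysis) in wild-type cells, 0.00272 (cytolytic), 0.714 (NK identity) and 0.0028 (glycolysis) in Mirc11-/- cells, 0.192 (cytolytic), 0.00299 (glycolysis), 0.0229 (interferon) and 0.478 (stress response) for the interaction, 0.714 (NK identity), 0.533 (glycolysis) and 0.714 (stress response) in stimulated cells and 0.944 (stress response) on average. Genes that changed direction were Gzmb (0.025 log2) in wild-type cells, Cd22 (-0.065), Xcr1 (-0.84), Slc1a5 (0.192), Hk2 (0.038), Bst2 (0.541), Ifit2 (0.297), Isg15 (0.734), Xaf1 (0.109) and Mcpt8 (0.225) in Mirc11-/- cells, and Cdk15 (-0.031) between stimulated genotypes. The vomeronasal level did not overlap between treatments within a genotype or between stimulated genotypes. A call lost under the covariate therefore does not show by itself that background made the change.

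Leaving out each library in turn, where a group of 2 libraries shares the spread of the others, gave 3931 to 4932 genes for stimulation in wild-type cells, 6760 to 8118 in Mirc11-/- cells, 0 (without unstimulated Mirc11-/- replicate 2, among others) to 19 (without stimulated wild-type replicate 1) for the interaction, 72 to 149 between unstimulated genotypes, 337 to 2397 between stimulated genotypes, 680 to 1491 on average and 53 to 62 lists. Differences in median log2 fold change between genes with and without a site on average ranged from 0.0266 to 0.0568 for miR-23a and from 0.0264 to 0.0577 for miR-27a. In unstimulated cells they ranged from -0.00699 to 0.0225, from -0.00697 to 0.0104 and from -0.0164 to 0.000373 for miR-23a, miR-27a and miR-24, so that the sign of this raw difference depended on single libraries (lowest without unstimulated wild-type replicate 2). The excess over the shuffles' median was positive in every setting there, at lowest 0.00506, 0.00573 and 0.00166 for the same microRNAs. Over all settings, adjusted p values of microRNA sites, which rank a difference among shuffled sites, were on average 0.0571 to 0.225 for miR-23a and miR-27a and 0.0875 to 0.244 for miR-24. In unstimulated cells they were 0.0571 to 0.171, 0.06 to 0.225 and 0.06 to 0.358 for miR-23a, miR-27a and miR-24, and in stimulated cells 0.0643 to 0.225, 0.0875 to 0.225 and 0.0643 to 0.308. At this depth Mir27a had 13 counts and Mir23a 0 over all libraries, too few to test the cluster's own transcripts.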

Other observations

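NK identity genes divided in stimulated wild-type cells. Cd27, a receptor of less mature NK cells, and the transcription factor gene Tbx21 rose by 1.70 and 0.75 log2, while Klrb1c (NK1.1), Itga2 and the activating receptor gene Ncr1 fell by 1.38, 1.18 and 0.98, so that 7 of 25 rose and 7 fell (9 and 7 adjusted over the list alone; list adjusted p = 0.813). In Mirc11-/- cells 3 rose and 9 fell, also when adjusted over the list alone, among them Klrb1c, Ncr1, Cd244 and Eomes by 1.67, 1.46, 1.27 and 0.91 (0.0276, and adjusted p = 0.583 with an estimated correlation; 0.14 without stimulated Mirc11-/- replicate 1). Between stimulated genotypes Klrg1, Id2, Fcgr3 and Eomes, which mark or drive NK maturation, were lower (Id2, Fcgr3 and Eomes fell by 0.82, 0.80 and 0.55 log2) among 5 of 25 (2 higher and 5 lower adjusted over the list alone; 0.0155, and adjusted p = 0.569 with an estimated correlation; 0.0985 without stimulated Mirc11-/- replicate 1). Under the background covariate these list tests changed direction (0.714 in both), the calls of Klrg1, Id2, Fcgr3 and Eomes between stimulated genotypes ended (-0.51, -0.32, -0.35 and -0.37 log2), and so did that of Eomes with stimulation in Mirc11-/- cells (-0.59). In a fit of the stimulated libraries alone the calls of Id2, Fcgr3 and Eomes ended (0.063, 0.0601 and 0.0533). On average 2 rose and 4 fell (3 and 6 adjusted over the list alone; 0.507), and in the interaction edgeR called 0, with 5 lower adjusted over the list alone (3.19e-05, and adjusted p = 0.388 with an estimated correlation). The activation and checkpoint list had 6 up and 6 down of 20 in wild-type cells (8 and 8 adjusted over the list alone; 0.535), with Irf4 2.76 log2 higher and Cd69 lower. It had 7 and 8 in Mirc11-/- cells (0.1; 0.0284 without unstimulated replicate 2), 0 and 0 in the interaction (0 and 3 adjusted over the list alone; 0.00754, and adjusted p = 0.347 with an estimated correlation), 0 and 1 in unstimulated cells (0.302) and 1 and 6 on average (1 and 7 adjusted over the list alone; 0.00477, and adjusted p = 0.347 with an estimated correlation).

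Some genes of the chymase and granzyme cluster on chromosome 14, singled out after their values were seen and not tested as a group, were lower in Mirc11-/- cells on average. Ctsg (56099881 to 56102574), Mcpt8, Gzmg and Gzmf (56205263 to 56211417) are neighbours, and Mcpt8, Gzmg and Gzmf fell by 1.40, 1.59 and 1.86 log2. Gzmb, in the same cluster (56258838 to 56262260), was not called (-0.14 log2, adjusted p = 0.508). Gzmf had 1274 ± 306 CPM in unstimulated wild-type and 400 ± 106 CPM in unstimulated Mirc11-/- cells (SD, n = 3). Among neutrophil and mast-cell markers, whose cells of origin in these cultures were not tested, 2 of 4 fell on average (Mcpt8 and Cpa3), also when adjusted over the list alone (7.54e-05, and adjusted p = 0.155 with an estimated correlation), 2 in stimulated cells (0.00148, and adjusted p = 0.291 with an estimated correlation) and 1 in unstimulated cells (0.000459, and adjusted p = 0.203 with an estimated correlation). Stimulation changed 1 up in wild-type cells (Kit; 0.34) and 1 up and 1 down in Mirc11-/- cells (0.779). T-cell markers were higher in Mirc11-/- cells on average, 3 of 12 (6 adjusted over the list alone; 0.000539, and adjusted p = 0.372 with an estimated correlation), with Cd8b1, Bcl11b and Cd8a 1.54, 1.08 and 1.04 log2 higher. Cd8b1 and Bcl11b were at low levels. In unstimulated and stimulated cells Cd8b1 averaged 0.574 and 0.595 CPM in wild-type and 1.34 and 2.13 CPM in Mirc11-/- libraries. Bcl11b averaged 1.93 and 1.25 against 3.93 and 2.75 CPM. The abundant member Trbc1 was not higher, at 231 and 230 CPM in wild-type and 216 and 187 CPM in Mirc11-/- libraries. The T-cell list's adjusted p with the background covariate was 0.000563, and the calls of Bcl11b (0.87 log2, 0.182) and Cd8a (0.93, 0.267) ended, as did those of Cd8b1, Cd6 and Bcl11b between stimulated genotypes (1.86, 1.57 and 0.73 log2). A fit of the stimulated libraries alone also ended the calls of Cd6, Bcl11b and Cpa3 (0.0796, 0.102 and 0.0851). The calls of Gzmg (-1.06 log2) and Cpa3 (-0.69) ended too, and those of Mcpt8 and Gzmf did not (0.0292 and 0.046). T-cell markers had 3 higher in stimulated cells (4 adjusted over the list alone; 0.0123, and adjusted p = 0.468 with an estimated correlation; up to 0.0935 in leave-outs, without stimulated wild-type replicate 3), 0 in unstimulated cells (3 adjusted over the list alone; 0.000201, and adjusted p = 0.352 with an estimated correlation), and 2 up with stimulation in wild-type and in Mirc11-/- cells (0.266 and 0.34).

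On average in Mirc11-/- cells 1 of 17 cytokines rose and 4 fell (1 and 8 adjusted over the list alone; 0.00158, and adjusted p = 0.352 with an estimated correlation), 4 of 21 NF-kB genes fell (7 adjusted over the list alone; 0.000748, and adjusted p = 0.426 with an estimated correlation) and 7 of 25 AP-1 genes fell (15 adjusted over the list alone; 3.47e-05, and adjusted p = 0.372 with an estimated correlation). Cytolytic genes had 1 up and 8 down of 20 (1 and 9 adjusted over the list alone; 8.53e-09, and adjusted p = 0.353 with an estimated correlation), cholesterol genes 17 down of 20 (19 adjusted over the list alone; 8.85e-16, and adjusted p = 0.242 with an estimated correlation), glycolysis 3 down (13 adjusted over the list alone; 8.63e-08, and adjusted p = 0.389 with an estimated correlation), and the stress response 3 down of 18 (13 adjusted over the list alone; 2.9e-06, and adjusted p = 0.397 with an estimated correlation). Of these, only the cholesterol list passed with the background covariate (3.71e-06); the stress response changed direction (0.944), and the cytokine, NF-kB, AP-1, cytolytic and glycolysis lists had 0.374, 0.38, 0.515, 0.0773 and 0.533, as the activation list had 0.326. In unstimulated cells the cytolytic list had 1 up and 1 down (1 and 5 adjusted over the list alone; 0.0019, and adjusted p = 0.569 with an estimated correlation; 0.081 without unstimulated wild-type replicate 2), NF-kB genes 0 and 1 (1 and 3 adjusted over the list alone; 0.34), AP-1 0 and 0 (0.635) and the stress response 0 and 0 (0.372). No member was called by edgeR in unstimulated cells for cholesterol (1 lower adjusted over the list alone; 6.59e-05, and adjusted p = 0.426 with an estimated correlation), glycolysis (0.00301, and adjusted p = 0.58 with an estimated correlation; up to 0.14 without unstimulated wild-type replicate 2) and the cell cycle (0.0122, and adjusted p = 0.623 with an estimated correlation; up to 0.457 without unstimulated Mirc11-/- replicate 2). The cell-cycle list had 1 lower member in stimulated cells (0.644) and on average (0.131) and 0 in the interaction (0.302). It passed in 1 of 6, 3 of 12 and 4 of 12 leave-outs in these contrasts (0.0102 and 0.00105 without stimulated Mirc11-/- replicate 1, and 0.0111 without unstimulated Mirc11-/- replicate 1).

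In the interaction, where no member of these lists passed over all genes in the main edgeR fit, the cytolytic list had an adjusted p of 3.53e-05 (adjusted p = 0.468 with an estimated correlation), the stress response 6.43e-09 (3 lower adjusted over the list alone; adjusted p = 0.352 with an estimated correlation), glycolysis 0.00023 (adjusted p = 0.505 with an estimated correlation) and NKG2D proximal signalling 0.0104 (adjusted p = 0.405 with an estimated correlation). Herpud1, of the stress response list and within 20 Mb of the deleted locus, passed in 2 of 23 alternative settings (lowest adjusted p 0.0136). Glycolysis passed with the background covariate in the opposite direction (0.00299), the cytolytic and stress response lists changed direction without passing (0.192 and 0.478), and NKG2D proximal signalling, NK identity, activation and heat-shock lists did not pass (0.844, 0.325, 0.909 and 0.379). NKG2D proximal signalling had 4 up and 5 down of 20 in stimulated wild-type cells (0.464), 3 and 10 in Mirc11-/- cells (0.0622, and past the threshold in 4 of 6 leave-outs, 0.0287 without stimulated replicate 2), 0 and 0 in unstimulated cells (2 higher adjusted over the list alone; 0.303), 0 and 2 in stimulated cells (0.118, and 0.0383 without stimulated wild-type replicate 2) and 2 and 1 on average (0.567). Glycolysis and nutrient transport had 1 up and 3 down with stimulation in wild-type cells (1 and 2 adjusted over the list alone; 0.415) and 1 and 7 in Mirc11-/- cells (0.0123, and adjusted p = 0.623 with an estimated correlation; 0.184 without stimulated Mirc11-/- replicate 1), and with the background covariate it passed in the opposite direction in both (0.0348 and 0.0028). Earlier-named targets had 5 up and 2 down of 19 with stimulation in wild-type cells (0.21), 6 and 4 in Mirc11-/- cells (0.274), 0 and 0 in the interaction (0.832) and in unstimulated cells (0.294), and 2 and 1 in stimulated cells (0.415). Interferon-stimulated genes had 1 and 1 of 20 (0.34; 0 and 0 adjusted over the list alone), 0 and 4 (0.266; 0 and 2 adjusted over the list alone) and 0 and 0 (0.464) in those contrasts, and Bst2 alone fell in unstimulated (0.112), stimulated (0.762) and averaged (0.317) comparisons of genotype, the first of these calls ending in 5 of 6 leave-outs (up to 0.157, without unstimulated Mirc11-/- replicate 2). Leaving out unstimulated wild-type replicate 2 brought the interferon list past the threshold in unstimulated cells (1.38e-06), on average (0.00567) and in the interaction (0.00656), leaving out unstimulated wild-type replicate 3 did so for stimulation in wild-type cells (0.0266) and stimulated wild-type replicate 2 in stimulated cells (0.0319). It passed with the background covariate in stimulated cells (0.000759), on average (0.0028) and, in the changed direction, in the interaction (0.0229). Heat-shock and RNA-quality genes had 1 and 4 of 15 (0.338), 3 and 3 (0.828), 0 and 0 (0.0395, and adjusted p = 0.318 with an estimated correlation; up to 0.1 without unstimulated wild-type replicate 2), 0 and 0 in unstimulated cells (0.0905; 0.0423 without unstimulated wild-type replicate 1), 0 and 1 in stimulated cells (0.474) and 0 and 1 on average (0.828), and the direction of their test and of their mean differed in all of these contrasts but stimulation in wild-type cells.

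Of the other cell types, B-cell markers had 3 of 6 higher with stimulation in wild-type cells (0.0783; 0.0277 without stimulated replicate 3), 1 higher in stimulated Mirc11-/- cells against wild type (Pax5, a call that ended in 5 of 6 leave-outs, up to 0.152; 2 adjusted over the list alone; 0.0701) and 0 in unstimulated cells and on average (0.784 and 0.34). Dendritic-cell markers had 3 of 7 higher with stimulation in wild-type cells (0.0662; 0.0308 without unstimulated replicate 3) and 1 higher between stimulated genotypes (Ccr9, a call that ended in 5 of 6 leave-outs, up to 0.17; 0.386). Both calls also ended in a fit of the stimulated libraries alone (0.0793 and 0.121). Macrophage and monocyte markers had 1 and 3 of 4 higher with stimulation in wild-type and Mirc11-/- cells (0.294 and 0.194), 0 in unstimulated (0.124; 0.0398 without unstimulated Mirc11-/- replicate 1) and stimulated comparisons of genotype (0.828) and 1 lower on average (Cd14; 0.362). Of 2 measured erythroid and platelet markers, Itga2b was called 0.79 log2 higher on average (adjusted p = 0.0483), a call that ended in 11 of 12 leave-outs. Of 6 measured genes beside the deleted locus, 3 rose with stimulation in wild-type and in Mirc11-/- cells (0.122 and 0.299), 0 passed in the interaction (0.762), 2 rose and 1 fell in unstimulated cells (3 and 1 adjusted over the list alone; 0.147), 1 and 1 in stimulated cells (3 and 1 adjusted over the list alone; 0.556) and 3 and 1 on average (0.278).

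Splits of the libraries were counted for the other comparisons. Exchanging libraries between 2 groups of 3 allows 10 splits, too few for a share under 0.05, and 1 of 10, the real one, was as large in each, with 5559 genes against 0 in the highest other for stimulation in wild-type cells, 7958 against 0 in Mirc11-/- cells, 193 against 1 between unstimulated and 1575 against 3 between stimulated genotypes. For the averaged genotype contrast 1 of 100 drawn splits, the real one with 1285 genes, was as large, with 183 in the highest other, so chance can be excluded at that number.

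Gm10925, a nuclear copy of mitochondrial sequence, had 1255 to 1926 CPM in the 6 unstimulated libraries and 0 counts in all 6 stimulated libraries, at least 26300-fold lower in wild-type and 29000-fold lower in Mirc11-/- cells against floors of 3 counts over the group (0.0493 and 0.0573 CPM). The mitochondrial gene mt-Atp6, which shares 99.5% of its 31-mers with other transcripts, had 29.7 to 143 CPM in unstimulated and 1632 to 2129 CPM in stimulated libraries. The labels give no batch, and a difference in handling or read assignment between stimulated and unstimulated libraries would be carried by the stimulation contrasts. Gm10800 ranged from 110 to 609 CPM in unstimulated and from 3891 to 34850 CPM in stimulated libraries. Mitochondrial rRNA mt-Rnr2 took 10.4 to 12.1% of counts in unstimulated Mirc11-/- against 9.16 to 9.84% in unstimulated wild-type libraries, and 13.8 to 14.4% against 12.6 to 13.6% in stimulated ones. All mitochondrial genes took 13.4 to 16.1% against 12.3 to 13.2%, and 16.4 to 18.8% against 15.2 to 16.4% (16.45 against 16.38 at the nearest). Total counts were lower in every Mirc11-/- library (15139281 to 18528612) than in any wild-type library (18892771 to 25342991). The mitochondrial share, a sign of RNA quality, and depth thus went with genotype, and the mitochondrial share also with stimulation; their part in the differences between groups was not tested. Rn7s1 took 3.09 to 4.71%. The first 2 principal components held 55.6% and 12.4% of the variance.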
